A study of Rattus norvegicus with 6 samples.

How the data were processed

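Islets were isolated by infusing collagenase into the common bile duct, per the labels' protocols, after which each perfused pancreas was cut into head and tail parts that were digested apart, purified on a density gradient and picked by hand. Total RNA was freed of ribosomal and transfer RNA, amplified by random priming and labelled with Cy3, per the labels' protocols. The intensity values were deposited as scanner output of Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes, with a background-subtracted and spatially detrended signal for each of 43217 spots per array, per the file headers. The authors' deposited value table of 38862 rows holds log2 values with the same quartiles in all 6 columns (median of each column 5.04), so that its scale is log2 and its arrays were made alike by quantile normalization, judging by the values. Its smallest values lie between 5.00 and 5.13 on the linear scale, and how it was floored is not given in the sources used here. Each of its columns correlated best with the scanner values of its own array (Pearson r 0.979 to 0.985 over probes). No column of another sample was present.

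From the scanner files, control spots and spots marked as non-uniform or population outliers were left out (130 to 177 spots per array besides controls). Spots of a probe were averaged on the log2 scale, and each array's 75th percentile over probes was subtracted. A probe was tested if it was well above background on at least 3 of the 6 arrays and had at least 2 values per region, which left 32183 of 38804 probes. Head minus tail was fitted with limma 3.58.1 (lmFit and eBayes with a variance trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The test is two-sided. A probe above background on no array of a region has only a bound there: its fold is given as at least the bright region's mean over the dim region's mean of, per array, the higher of its own signal and the lowest signal of a probe well above background.

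The scanner files give an accession only for 50 probes of the Agilent catalogue, 30 of which matched a symbol in the RefSeq table of assembly GRCr8 through accessions without versions, and 27 of these were tested. The other probes have design identifiers without gene names here. Those beginning with ASRN6AP (28287 probes) were taken as protein-coding, and those beginning with ASRN6LNC (3855), ASRNV (5519) or uc (959) as lncRNA. This split is an inference from the identifiers, since no table used here states the class of a probe. A further 102 probes beginning with ASSPINKEIN and 32 beginning with CUST, each in 20 spots, have an unknown target and count only among all probes. The test of gene lists (37 lists) needed at least 5 tested named genes per list, which 0 lists had, and 0 islet hormone genes were nameable, so neither could be run.

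The rule for named genes, fixed before the data were examined with the groups, the alternatives and the main fit, took genes past the threshold with no overlap, then those of smallest p with an absolute log2 difference of at least 1 and no overlap. Only Slc28a2 met it. All other nameable genes were therefore described as well, a choice made after the data were examined. They are given by name where they differed by at least 1 standard error of the fit without the block, and as a range otherwise. The SE of a gene is that of this fit unless the block is named. For lncRNA the rule left 47 probes higher and 600 lower in the head, of which 2 identifiers are given because the probes have no names.

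Same-numbered head and tail arrays deviated together: the correlation over probes of their deviations from the region means was 0.51, 0.75 and 0.29 for numbers 1, 2 and 3, and each array correlated best with its own number in the other region. With the protocol's cutting of each pancreas into both parts, the numbers were taken to pair the samples. Only 6 pairings of the arrays exist, so this agreement alone is weak evidence of pairing. For number 3 it was narrow, since tail replicate 3 reached 0.22 with head replicate 2. The fit with the replicate number as a block is given where it changes a call. Judging by a scan identifier in the file headers, the arrays lay on 3 slides. The 3 tail arrays were on the first, head replicate 1 on the second and head replicates 2 and 3 on the third. Slide was used as a random block (duplicateCorrelation) in 1 alternative. Since no slide held both regions, that block cannot correct the head and tail contrast for slide.

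The spots of a catalogue probe on an array had a median SD of 0.097 log2 units, which does not cover the noise of labelling and hybridisation that the spots of an array share. The fit was tested on simulated data for the 32109 probes with 6 values, in which 200 probes were changed, 50 per size. Values were drawn with the real means and the variances as shrunken by eBayes, and with an assumed replicate effect for the blocked fit. Noise was normal and independent between probes, whereas probes of the real arrays vary together. Shrinkage also draws the variances of probes together. The shares recovered therefore need not hold for the real data. Without the block, 4% of log2 changes of 1, 58% of 2, 98% of 3 and 100% of 4 were recovered, with 8 unchanged probes called. With the block, 22%, 98%, 100% and 96% were recovered, with 14 unchanged probes called. In the real fit without the block, ASRN6AP1B100026125V3 and ASRN6AP1B100086128V3 differed by 3.99 and 4.14 and did not pass (limma adjusted p = 0.211 each). The lack of calls there therefore does not show that changes of 3 or 4 are absent.

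The alternatives were quantile normalization, median centring, normexp background correction (offset 50) with quantile normalization, the authors' deposited value table, no filter or a stricter filter on dim probes, the replicate and slide blocks, no variance trend, array quality weights, an unequal-variance test per probe, a threshold of an unadjusted p under 0.05 with a fold of at least 2, and leaving out each sample. Normexp used the median spot signal, because the planned mean signal is not among the columns used here. Its offset draws dim signals together whatever the data, so its smaller differences are no estimate of size. Some fits were added after the data were examined: the replicate block with quantile normalization, the threshold of an unadjusted p with the block, the recomputation of family medians, the gap between the families within pairs, the control probes against coding probes of matched signal, and array weights and slide block on other splits of the samples.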

Results

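Messenger RNA and long noncoding RNA (lncRNA) were measured in pancreatic islets, the hormone-secreting cell clusters of the pancreas, isolated separately from the head (duodenal part) and the tail (splenic part) of the pancreas of male rats. The comparison asks how islets of these 2 regions differ in their transcripts. Each region had 3 samples, numbered 1 to 3, and each sample was hybridised to 1 single-colour array with 38804 probes other than controls. The 75th percentile of the probe signal was 264, 114 and 117 on the arrays of tail replicates 1, 2 and 3, and 203, 207 and 259 on those of head replicates 1, 2 and 3. Between 30378 and 33567 probes per array were well above background (78.3% to 86.5%), and no spot was saturated. The number of arrays limits the precision, and the labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples.

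Most probes carry only a design identifier here, so genes could be named for 27 probes of the array maker's catalogue that were bright enough to test, each printed in 10 spots. Of these 27 genes, 22 had a higher mean in head islets, and 19 differed by at least 1 standard error, 17 higher and 2 lower in the head. Over all tested probes the median difference was -0.23. Catalogue probes are brighter (median level -0.66, against -1.77 for probes taken as protein-coding), so this lean is not read as particular to these genes. The regions did not overlap for 6 of the 27 genes, against 24.9% of all probes. The head array was the higher in all 3 same-numbered pairs for 14 of the 27 and the lower in all 3 for 2. The share of all probes that do so was not computed. No named gene passed the adjusted threshold in the limma fit. The largest difference under this scaling was that of Slc28a2 (NM_031664), a concentrative nucleoside transporter. Its log2 signal relative to the array's 75th percentile was 1.31 ± 0.56 in head and 0.08 ± 0.46 in tail islets (SD, n = 3 each). After quantile normalization its difference was 1.11, under those of Cyp2e1 at 1.25 and LOC108352165 at 1.16. The head level of Slc28a2 was 2.34-fold the tail level (log2 difference 1.23, SE 0.40, limma adjusted p = 0.22), and the arrays of the regions did not overlap. With the replicate number as a block its SE was 0.25 and its adjusted p 0.0641 over all probes. Adjusted over the 27 nameable genes alone, a set not fixed beforehand, the blocked fit gave 0.0457.

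Enpp1 (NM_053535), which encodes an ectonucleotide pyrophosphatase of the cell surface, stood at -0.11 ± 0.20 in head and -1.06 ± 0.35 in tail islets, a log2 difference of 0.95 (SE 0.29, limma adjusted p = 0.211) with no overlap of the arrays. P2rx2, an ATP-gated cation channel, was 1 of the 2 among these 19 genes with a lower mean in the head. Its difference was -0.48 (SE 0.32) with overlapping arrays, and -0.13 after quantile normalization and -0.047 with normexp background correction. In pair 3 its head array was the higher, at -3.18 against -3.32. The other was Med16, a subunit of the Mediator complex of transcription, at -1.19 ± 0.26 in head against -0.69 ± 0.15 in tail islets, a difference of -0.50 (SE 0.26) without overlap.

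Ldha, lactate dehydrogenase A, which beta cells normally keep low, differed by 0.82 (SE 0.35), with 0.33 ± 0.35 in head and -0.49 ± 0.49 in tail islets, and the head array was higher in each same-numbered pair although the regions overlapped. Cyp2e1, an ethanol-metabolising cytochrome P450, differed by 0.89 (SE 0.44) and Nat1, an arylamine N-acetyltransferase, by 0.59 (SE 0.27), both without overlap. For Cyp2e1 the distance came largely from tail replicate 1, at -4.78, against -3.31 and -3.11 on the other tail arrays.

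Ndfip2, an adaptor that recruits Nedd4-family ubiquitin ligases, stood at 2.17 ± 0.21 in head and 1.34 ± 0.21 in tail islets, a difference of 0.84 (SE 0.31) without overlap. Trim2, an E3 ubiquitin ligase, differed by 0.80 (SE 0.42), and its head array was higher in each of the 3 pairs. Pld1, phospholipase D1, differed by 1.00 (SE 0.42) and was also higher in the head in each pair, with 0.73 ± 0.45 against -0.28 ± 0.66. Pdcd10, a scaffold protein of signalling kinases, differed by 0.69 (SE 0.42), and Cdh2, the adhesion protein N-cadherin, by 0.69 (SE 0.66), with tail replicate 1 at -0.57 and the other tail arrays at -2.71 and -3.06.

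Magoh, a core protein of the exon junction complex, differed by 0.69 (SE 0.38), the translation initiation factor Eif4b by 0.52 (SE 0.46), the RNA-binding ubiquitin ligase Mex3c by 0.48 (SE 0.35), Pop7, a subunit of RNase P and RNase MRP, by 0.46 (SE 0.39), and the nuclear export factor Cse1l by 0.42 (SE 0.41). Odf2l differed by 0.61 (SE 0.39), and LOC108352165, an uncharacterised transcript that was well above background on 3 head arrays and 1 tail array, by 0.72 (SE 0.49). The remaining 8 genes differed by less than 1 standard error of the fit without the block, between -0.27 and 0.34. This cut ignores the pairing. With the replicate number as a block, Ndfip1 (0.34, SE 0.28) and Dlg4 (-0.27, SE 0.21) would also exceed 1 standard error. Gdnf, Lhcgr and Nlrp3 were well above background on 0 of the 6 arrays. The adjusted p of the 19 genes lay between 0.211 and 0.526 in the limma fit, and quantile normalization kept the direction of all 19. Their sizes were less stable: leaving out 1 array moved the difference of 11 of the 19 genes by over 1.5 times in at least 1 case. Normexp background correction brought that of 10 genes closer to 0 by as much, which its offset would do whatever the data. Without tail replicate 1 the difference of Eif4b was 0.16, and without tail replicate 2 those of Cse1l and Mex3c were 0.16 and 0.23.

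**Figure D1:**
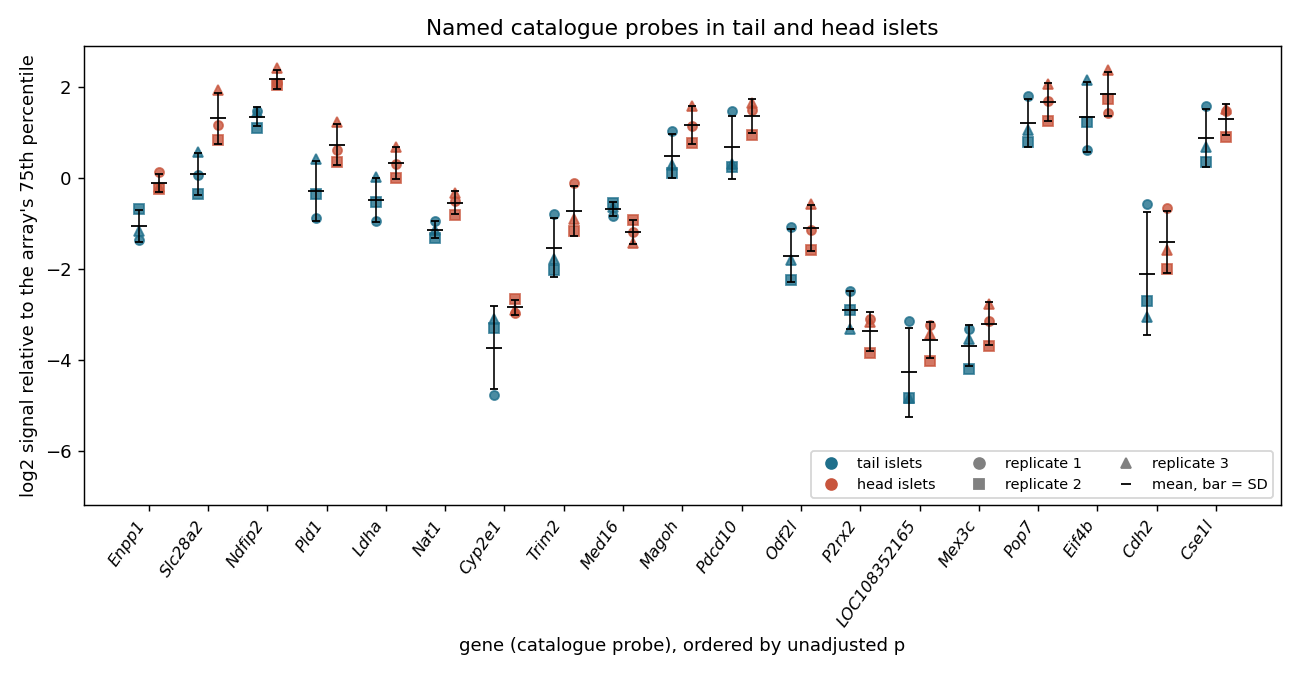
Log2 signal relative to the array's 75th percentile (vertical axis) for the 19 named genes that differed by at least 1 standard error (horizontal axis), with a point for each array (blue, tail; red, head; the shape gives the replicate number) and the mean with its SD in black. The head points of Enpp1 and Slc28a2 lie above every tail point of the same gene, while those of Cdh2 and Pop7 overlap.

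Across all probes, 0 of 32183 tested probes differed between head and tail islets at an adjusted p of 0.05 in the limma fit, in which the smallest adjusted p was 0.211. At an unadjusted p under 0.05, 6169 probes (19.2%) differed. Other scalings gave lower shares, 15% with median centring, 11.7% with quantile normalization or normexp, and 11.6% in the authors' deposited value table. Over probes with 6 values the share was 19.1%, against 37% when tail replicate 1 and head replicates 1 and 3 were set against the rest, and 0.0156% to 5.49% in the 8 remaining splits of the arrays into 3 and 3, 1.91% at most in those that part all 3 same-numbered pairs. The arrays of the regions did not overlap for 7980 of the 32109 probes with a value on every array (24.9%, where the 10 splits average 10%). With the replicate number as a block, 1 probe passed, ASRN6AP1B100026125V3 of the coding family, and 33.7% of probes had an unadjusted p under 0.05. Array quality weights gave 14407 probes and slide as a random block 6057, and up to 22073 and 9134 passed when the same fits were run on other splits of the 6 arrays. The within-slide correlation behind the 6057 was estimated at -0.32. Those calls are not read as corrected for slide. Leaving out tail replicate 3 gave 3 probes at the adjusted threshold, and the share at an unadjusted p under 0.05 ranged from 6.94% without tail replicate 2 to 42.6% without tail replicate 1. No slide held arrays of both regions, so no value within a slide could be had.

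An unadjusted p under 0.05 with a fold of at least 2 held for 2571 probes, 745 higher and 1826 lower in head islets. This direction depends on the scaling. The median log2 difference over all tested probes was -0.23 after scaling to the 75th percentile, and 29.0% of the 2571 probes were higher in the head. After quantile normalization the median was -0.06, and 942 probes were higher and 642 lower (59.5% higher), and after median centring the median was 0.03, with 1896 higher and 551 lower (77.5% higher). With normexp, whose offset shrinks differences, 185 probes were higher and 216 lower. Without tail replicate 1 the count in the main scaling was 7148, and without tail replicate 2 it was 1414. Among the largest differences more probes were higher in head islets under each scaling: with no overlap between the arrays of the regions, 70 probes were at least 4-fold higher and 31 at least 4-fold lower, against 113 and 6 after quantile normalization, 122 and 8 after median centring, and 7 and 0 after normexp background correction with quantile normalization.

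The arrays grouped in part by region and in part by replicate number, and their plain correlations followed the number clearly only for number 1. Tail replicate 3 was closer to head replicate 2 (0.971) than to head replicate 3 (0.94). Head replicate 3 was closer to tail replicate 1 (0.948). The closest arrays were tail replicates 2 and 3 (Pearson r over tested probes 0.981), followed by tail replicate 1 with head replicate 1 (0.975), while tail replicate 1 reached 0.934 and 0.931 with the other tail arrays. The labels were taken as given, and whether tail replicate 1 is labelled rightly could not be settled from these values, which bears on each head and tail difference reported here. Of the sum of squares over probes, 32.7% lay between regions, 50.0% between replicate numbers and 17.3% in the remainder, where values without structure would give 20% and 40% for the first 2.

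**Figure D2:**
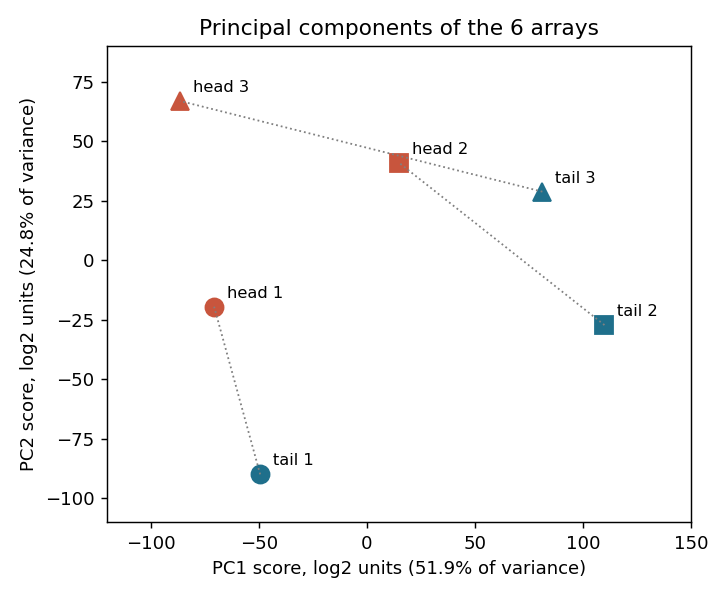
Scores of the 6 arrays on the first (horizontal axis, 51.9% of the variance) and second principal component (vertical axis, 24.8%) of the log2 signals, coloured by region (blue, tail; red, head), with the shape giving the replicate number and dotted lines joining arrays of the same number. Tail replicates 2 and 3 lie at 109.9 and 81.2 on the first component, and tail replicate 1 lies at -49.3, among the head arrays. On the second component tail replicate 1 lies lowest, at -89.9.

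In the family of 28287 probes taken here as protein-coding from their identifiers, 25134 were tested and 0 passed the adjusted threshold in the limma fit. An unadjusted p under 0.05 held for 4278 (17.0%), a share that was 14.8% after median centring and 11.1% after quantile normalization. With the replicate block 1 passed. That probe, ASRN6AP1B100026125V3, was well above background on all 3 head arrays and on 0 tail arrays. Its mean was -1.40 ± 0.53 in head and -5.39 ± 0.55 in tail islets (SD, n = 3 each), so its head level was at least 12-fold the tail level (limma adjusted p = 0.211, and 0.0199 with the block). This bound holds without an offset. Normexp background correction adds one that draws dim signals together, and the 1.19 log2 units between the regions there are no estimate of the fold. A further coding family probe, ASRN6AP1B100086128V3, singled out after its values were seen, passed together with it in the authors' deposited value table. It stood at -0.81 ± 0.51 in head and -4.95 ± 0.90 in tail islets, where 1 of 3 arrays was well above background (log2 difference 4.14, SE 0.47, limma adjusted p = 0.211). That difference rests in part on tail signals not well above background, so its size is uncertain, and it was 1.47 with normexp. An unadjusted p under 0.05 with a fold of at least 2 held for 683 coding probes higher and 1051 lower in the head, against 769 and 446 after quantile normalization and 1701 and 283 after median centring. Of the family, 66 probes were at least 4-fold higher in the head without overlap and 12 at least 4-fold lower, and 96 and 4 after quantile normalization. Array quality weights called 10621 coding probes and slide as a random block 4281. The family's median log2 difference was -0.14, and it was 0.01 after quantile normalization and 0.13 after median centring.

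In the family of 10333 probes taken as lncRNA from their identifiers, 6912 were tested and 0 passed the adjusted threshold in the limma fit, with or without the replicate block. Without it 1851 (26.8%) had an unadjusted p under 0.05, a share that was 15.8% after median centring and 13.9% after quantile normalization. Most of the family's differences pointed to lower levels in head islets. An unadjusted p under 0.05 with a fold of at least 2 held for 59 lncRNA probes higher and 766 lower in the head. After quantile normalization the numbers were 170 and 196, after median centring 183 and 267, and with normexp, whose offset shrinks differences, 7 and 36. The median log2 difference of the family was -0.50, against -0.25 after quantile normalization, -0.24 after median centring and -0.07 after normexp background correction with quantile normalization. On single arrays the family's median was -2.79, -2.38 and -2.43 in tail replicates 1, 2 and 3 and -3.09, -2.86 and -2.99 in head replicates 1, 2 and 3, without overlap, where 3 arrays against 3 cannot give an exact permutation p under 0.1. After quantile normalization the regions overlapped, with head replicate 2 at 4.81 above tail replicate 1 at 4.73, but the head array was the lower in each of the 3 same-numbered pairs. Control probes were also lower in the head relative to the 75th percentile: of 21 control names well above background on all 6 arrays, 20 had a lower mean in the head. Their median difference was -0.70, with -1.17 to -0.51 for the 4 E1A spike-ins, against -0.50 for the lncRNA family. These controls were dimmer than the lncRNA family (level -3.98 against -2.77), so the shifts are not compared at equal signal. Coding probes matched to the controls' level differed by -0.43.

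The lncRNA probes with the smallest p among those lower in head islets were ASRNV20032520V3 and ASRNV20028468V3, and neither passed the test. ASRNV20032520V3 stood at -3.87 ± 0.09 in head and -2.12 ± 0.12 in tail islets (SD, n = 3 each), so its tail level was 3.37-fold the head level (log2 difference -1.75, SE 0.22, limma adjusted p = 0.211). ASRNV20028468V3 stood at -4.51 ± 0.15 and -2.81 ± 0.15, a tail level 3.25-fold the head level (difference -1.70, SE 0.24). After quantile normalization these differences were -1.43 and -1.31. With normexp background correction, whose offset draws dim signals together, they were -0.46 and -0.26. The lncRNA probe with the smallest p among those higher in the head differed by 1.99 (SE 0.34), with -0.01 ± 0.41 in head and -2.0 ± 0.47 in tail islets, and did not pass. At least 4-fold differences without overlap were found in 4 lncRNA probes higher and 19 lower in the head, a direction that turned with the scaling, to 17 higher and 2 lower after quantile normalization and 11 and 4 after median centring. Array quality weights called 3700 lncRNA probes and slide as a random block 1737.

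**Figure D3:**
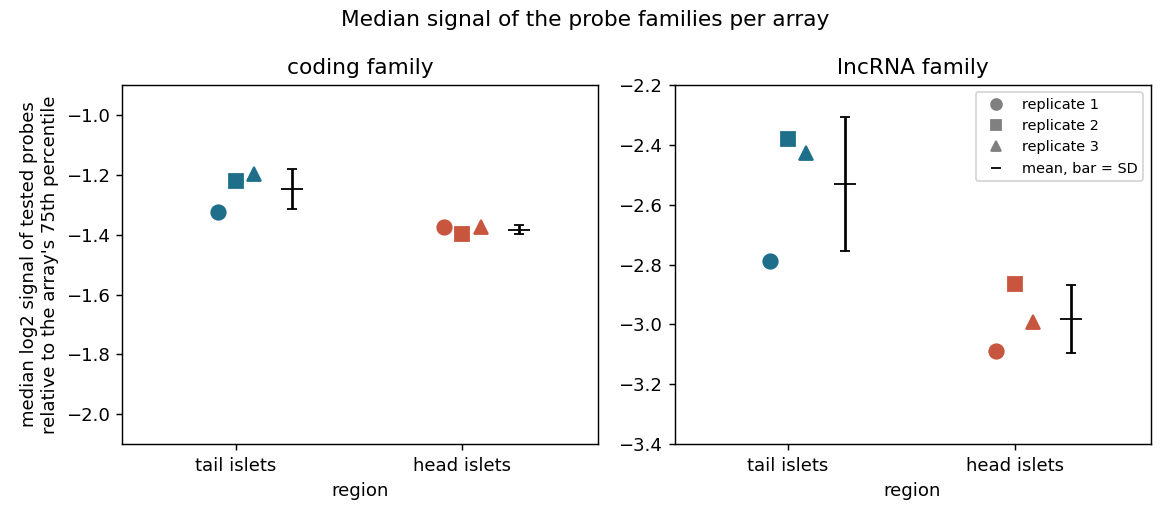
Median log2 signal of the tested probes of the coding family (left) and the lncRNA family (right), relative to the array's 75th percentile (vertical axis), for each array by region (horizontal axis), with the mean and SD of 3 arrays in black. The head arrays lie lowest in both panels, between -1.40 and -1.37 in the coding panel and between -3.09 and -2.86 in the lncRNA panel, and the vertical axes of the panels cover different ranges.

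The genes of the islet hormones and the lists of islet cell types, other pancreatic cell types and pathways could not be compared, because the probes of those genes are not paired with names here. Of the 37 lists fixed beforehand, none had over 1 tested named gene. Ldha belongs to the lists of glycolysis and hypoxia genes and of genes that beta cells normally keep silent, and Cyp2e1 to the list of liver genes. No statement on the mix of cell types in the preparations rests on these values.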

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

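Signal outside the main measurement was seen on control probes, which the comparisons leave out: of 58 control names, 21 were well above background on all 6 arrays, 4 of them named for E1A spike-in transcripts. Their mean head minus tail differences, relative to the 75th percentile, lay between -1.19 and 0.01 log2 units, with 20 of the 21 lower in the head, a median of -0.70, and -1.17 to -0.51 for the E1A names. Before that scaling 15 of the 21 were lower in the head and the median was -0.16, while the log2 75th percentile was 0.54 higher on the head arrays. Groups of 3 samples are too small to test a sample for standing apart.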

How the results depend on the processing

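The replicate block with quantile normalization, the block with the unadjusted threshold and the family medians were added after the data were examined. The count of 0 probes past the adjusted threshold held under normexp, quantile normalization, median centring, both filters, no variance trend and the unequal-variance test, in which 4234 probes had an unadjusted p under 0.05. The authors' deposited value table gave 2 probes, both of the coding family. The replicate block gave 1, of the coding family, with or without quantile normalization, and, with adjustment over all probes, changed no call of a named gene or of the lncRNA family. Over the 27 nameable genes alone the block took Slc28a2 from an adjusted p of 0.215 to 0.0457. Leaving out each replicate gave 0 to 3 probes, 0 to 3 of the coding family and 0 of the lncRNA family, with 3 only without tail replicate 3. Array quality weights, which gave tail replicate 1 a weight of 0.20 and tail replicate 3 a weight of 4.36, gave 14407 probes, 10621 coding and 3700 lncRNA. Slide as a random block gave 6057, 4281 coding and 1737 lncRNA, with a within-slide correlation estimated at -0.32, below 0. In that fit a negative value lowers the variance given to a mean of arrays on the same slide, as the tail arrays were, relative to that of a single array. An unadjusted p under 0.05 with a fold of at least 2 gave 2571, 1734 coding and 825 lncRNA, and 3300 over all probes with the replicate block. Beyond these constructions the cause was not tested.

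The median difference of the coding family, -0.14, was 0.00 with normexp, 0.005 with quantile normalization, 0.13 with median centring, 0.008 in the deposited table and -0.21 without a filter; that of the lncRNA family, -0.50, was -0.065, -0.25, -0.24 and -0.23 in the first 4 of these. Without single replicates they ranged from -0.17 to -0.11 and from -0.67 to -0.39. Of 322 recomputed values of the 19 named genes over 17 alternatives, 304 kept their direction and their side of the threshold and 17 came to pass it, 12 with array weights and 5 with the slide block. Eif4b turned to -0.044 with array weights, and the cause was not tested. Gene lists and islet hormones were not run under any alternative, for want of names. Signal over background limits the 6621 probes that were not tested.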

Other observations

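Tests chosen only after the result was seen were the splits of the fits without weights or slide, the replicate numbers and slides for the structure of the arrays, the slide for the excess of small p, the splits for the strand correlation, the label of tail replicate 1, the gap between the families within pairs, and the control probes. More probes were detected in the tail alone than in the head alone: 161 probes were well above background on all 3 tail arrays and on 0 head arrays, 69 of the coding and 91 of the lncRNA family, against 33 on all head arrays and no tail array, 25 coding and 8 lncRNA. These sum to 194, against 45, 7 and 35 in the other splits that part all 3 same-numbered pairs, and 477 in the split of tail replicate 1 with head replicates 1 and 3 against the rest, which parts 1 pair. The lean is not particular to the tail, since the side holding tail replicate 1, the array with most probes above background (86.5%), had more such probes in all 10 splits, with 450 against 27 in that split. After scaling to the 75th percentile, 0.333% of lncRNA probes differed at least 4-fold without overlap, against 0.311% of all coding probes and 0.466% of coding probes matched on mean signal, a ratio of 0.714 to the matched share.

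The array also holds probes for both strands of ultraconserved elements, stretches of genome nearly identical between mammals. Of 480 elements, 145 had both strands tested, and the hypothesis was that both strands differ together between head and tail. After removing the trend with signal, the head minus tail differences of the strands correlated over elements (Pearson r = 0.346, Spearman rho 0.377, permutation p = 1e-04 for Pearson's r, the smallest that 10000 permutations can give). Elements are not independent replicates. Of the 10 splits of the arrays, 1, the real one, gave a correlation as large, but the others ranged from -0.03 to 0.323, so strands may move together between arrays for reasons other than region.

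Chance cannot be judged from 10 splits of 6 arrays, since the share of splits is never under 0.1. The counts past the adjusted threshold were 0 for all, coding and lncRNA probes in the real split, and at most 4561, 3533 and 1011 in another. Any split reaches a count of 0, so this comparison decides nothing. At an unadjusted p under 0.05 with a fold of at least 2, over probes with 6 values, the real split gave 2532 and the highest other 5769, so that 2 of the 10 splits gave as many, while the other splits that part all 3 pairs gave 35, 4 and 420. Array weights gave 14359 in the real split and up to 22073 in another, with 3 of the 10 as large, and called 0 in 4 splits. Slide as a random block gave 6057 and up to 9134, with 2 of the 10 as large.

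The first pattern is the split of tail replicate 1, head replicate 1 and head replicate 3 against the other arrays, which called 4561 probes across regions and points to a structure of the samples. Slide is argued against, since the split divides both of the 2 slides that hold over 1 array. Scaling that depends on signal is argued against too, since quantile normalization left 5546 calls, 1.216 times as many, although the first component followed the log2 75th percentile of the arrays (Pearson r = -0.919, exact permutation p = 0.0208, adjusted over 2 relations 0.0417; Spearman rho -0.714, p = 0.136; r = -0.454 without the 2 arrays farthest from the median, so it rests on those). A shared animal or preparation behind each number may account for part of it, since the lowest correlation of deviations in a same-numbered pair was 0.287, and the split keeps pairs 1 and 2 together but parts pair 3. The split also followed detection. Tail replicate 1 and head replicates 1 and 3 had 86.5%, 81.6% and 82.4% of probes well above background. Tail replicates 2 and 3 and head replicate 2 had 79.6%, 80.6% and 78.3%. Technical differences between arrays that quantile normalization does not remove therefore stay open, as do differences between the animals or preparations.

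The second pattern is the lower level of the lncRNA family in head islets, relative to the coding family (gap between the medians -1.59 in head and -1.28 in tail islets, difference -0.31, SE 0.12, exact permutation p = 0.2). Whether dim probes were scaled unlike bright ones stays open. Against coding probes matched on mean signal the difference of the gap was -0.215, 68.7% of the unmatched one. It was -0.18, -0.17 and -0.29 in pairs 1, 2 and 3 (SE within pairs 0.038, exact sign-flip p = 0.25, the smallest 3 pairs allow; SE 0.12 ignoring the pairs, within 2 SE of 0), and -0.204 after quantile normalization and -0.07 with normexp (SE within pairs 0.041 and 0.015). By the SE within pairs, chosen after the result was seen, that would exclude such scaling as the whole cause, and by the other SE it would not. The 21 control names detected on all arrays, read the same way, also fell below coding probes of their own mean signal, by -0.293 (SE within pairs 0.051; -0.22, -0.268 and -0.391 in pairs 1, 2 and 3), which suggests that probes of equal signal need not be scaled alike. The 4 E1A spike-ins among them do not decide (-0.315, SE within pairs 0.37; -1.041, -0.075 and 0.171). The gap went with the log2 75th percentile of the array (Pearson r = -0.815, exact permutation p = 0.0625, also 0.0625 adjusted over 2 relations; Spearman rho -0.60, p = 0.242; r = 0.305 without the 2 farthest arrays), which leaves brightness open. A difference between the regions may also account for it and was not tested apart from these.

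The third pattern is the share of probes with an unadjusted p under 0.05 between the regions, 19.1% of those with 6 values, above the 0.0156% to 5.49% of 8 other splits but under the 37% of the split of the first pattern. Part of it depended on the scaling, since over all tested probes the share fell from 19.2% to 11.7% after quantile normalization. With 0 slides holding both regions, region and slide cannot be told apart. A regional difference of islets stays a hypothesis.

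A further hypothesis was that tail replicate 1, which lay nearer head replicate 1 than the other tail arrays, is mislabelled. Of probes that differed at least 4-fold in one direction in pairs 2 and 3, relative to each pair's median, 148 were read in pair 1, where 85.1% had the same direction and the median difference was 1.11, against 2.59 in pairs 2 and 3, a share of 0.429. Read the same way from the other pairs, pair 2 gave a share of 0.937 and pair 3 of 0.795. An exchange of the labels within pair 1 would have turned the direction. A tail array from another source, or a mixed sample, may still account for the smaller difference, as may a smaller difference in that animal.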
